A study of Caldicellulosiruptor bescii with 30 samples.

How the data were processed

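RNA was sequenced from batch fermenters of Caldicellulosiruptor bescii strain DSM6725, an anaerobic, thermophilic bacterium that breaks down plant polysaccharides. In 3 control fermenters the medium stayed at pH 7.2, and in 3 treated fermenters it was brought down to pH 6.0 with acid in the middle of exponential growth. Per the labels' protocols, ribosomal RNA was depleted before library preparation with a ScriptSeq kit. Per the submitters' processing notes, bcl2fastq 1.8.3 and DESeq2 were used. The aligner, the counting program, its strand setting, the genome build and the annotation are not given in the sources used here. The deposited table holds whole read counts per gene, not normalised, with 1 column per library and 2792 rows.

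Of the rows, 51 carry a gene symbol and 2741 only a locus tag. The table does not pair tags with names, so function was assigned to symbols alone, and 2 locus tags that rose and 2 that fell are printed without a name. There were 24 columns whose names matched exactly 1 sample label, from 6 fermenters at 5, 30, 60 and 90 min after acid addition. A further 6 columns match no sample label and were not used. The 6 samples labelled 10 min matched no column and were not analysed here, so the comparison planned at 10 min was not run. The unused columns are named for 0 min, a time that no label gives, so it stays open whether the columns named 5 min hold that time or the later 10 min sample. Groups were taken from the labels throughout, and each group holds 3 libraries, 1 per fermenter.

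Total counts per library ran from 7940256 to 15073941 in controls and from 8039990 to 18189508 in treated fermenters. No counting intervals were computed for single genes, and the standard errors below reflect the spread between fermenters as well as counting error. Libraries were compared in pairs by a chi-square statistic per degree of freedom over genes. The lowest value was 29.65, so no pair agreed within sampling noise, and every library was treated as a separate sample. A value above sampling noise does not show that a pair comes from different fermenters. The lowest value across fermenters was 53.8, between the libraries labelled control replicate 3 and treated replicate 1 at 5 min.

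Treated and control libraries were compared at each time with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the default expression filter of edgeR, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic. All adjusted p-values in the text come from this edgeR quasi-likelihood test unless another tool is named. Differences of the treatment effect between times were tested in an edgeR fit of all 24 libraries with the fermenter as a block, jointly over the times and as the contrast of 90 against 5 min. Change with time in control fermenters was tested in the control libraries with the same block. Both fits were planned with the samples labelled 10 min as well and were run without them. CPM values are counts scaled by library size and TMM factor, computed within each time.

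Before the data were examined, the tests, the processing alternatives, 30 gene lists and the rule for named genes were fixed. Only symbols could be matched to the lists: 18 lists held a symbol, 12 held none, and 1, the ribosomal proteins, held the 5 that a set test with camera in limma 3.58.1 needs. The lists without a symbol, the F-type ATP synthase among them, are not reported. Camera used a preset correlation of 0.01 between genes, and an estimated correlation as an alternative. The directional and mixed tests of fry in limma were planned as well. They ask if a set changed in a common direction or in any direction, without comparing it to other genes. The rule named, at each time, the 3 largest rises and the 3 largest falls among called genes with a mean of at least 10 CPM whose treated and control libraries did not overlap. It was applied to symbols. The rule for genes called with 1 sign at every time gave 0 genes, so the locus tags were instead taken from the 3 later times. Fewer were taken than planned, and the limits on CPM and overlap were added. These choices were made after the calls at 5 min were seen. A planned rule for the largest called changes in the tests over time was not applied, and no symbol was called in those tests. Other genes are named where a list or a small count calls for them, and were chosen after their values were seen: porA at 30 min, tuf, pheS, rplB, gatA and metX at 60 min, and the genes named without a call.

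The alternatives chosen beforehand were DESeq2 1.42.0, the size factors of DESeq2 in place of TMM, removal of the 10 most abundant genes, no expression filter, a filter of 10 CPM in 3 libraries, a joint fit of all libraries, limma-voom with the fermenter as a random effect, the replicate number as a block, the tests over time without the fermenter as a block, a minimum absolute log2 fold change of 1, and each library or fermenter left out in turn. Alternatives chosen after seeing the data leave out the library labelled control replicate 3 at 5 min and the library labelled treated replicate 2 at 5 min, or all of the 5 min libraries. Like the joint fit, limma-voom used the libraries of all times together, these 5 min libraries included. It was not run without them. Median log2 fold changes of all genes moved by -0.0241 to 0.0154 between TMM and the size factors of DESeq2.

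Each test was tested on simulated data, drawn from the observed means and library sizes with 100 genes changed 2-fold and 100 changed 4-fold. The spread between libraries was set per gene and pooled over all times. At 5 min, 20% of the 2-fold and 79% of the 4-fold changes were recovered among 2644 genes. At 30 min the shares were 20% and 78% of 2671 genes, at 60 min 24% and 88% of 2680 genes, and at 90 min 22% and 86% of 2685 genes. The joint test over times recovered 10% and 65%, and the contrast of 90 against 5 min 6% and 68%, both among 2698 genes. The control time test recovered 32% and 87% among 2692 genes. The share of false calls lay between 0% and 6.33%. The observed biological coefficient of variation was 0.415 at 5 min and 0.25 to 0.302 at the later times. The shares recovered in the comparison at 5 min are therefore likely too high. The simulation also gave libraries of the same fermenter no correlation, while it was 0.408 in the data by limma. For the tests over time it is therefore not known in which direction the shares are off.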

Results

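Transcript levels were measured by RNA sequencing in batch cultures of Caldicellulosiruptor bescii growing on maltose, to follow the response to a drop of the medium from pH 7.2 to pH 6.0. There were 3 control and 3 treated fermenters, each sampled at 5, 30, 60 and 90 min after acid addition, which gave 24 libraries in 8 groups of 3. Total counts per library ran from 7940256 to 15073941 in controls and from 8039990 to 18189508 in treated fermenters. The same fermenters were sampled at every time, so the times are repeated measures of 6 cultures.

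The treatment set the main axis of variation among libraries. Principal component 1 of log2 CPM held 50.2% of the variance over 2706 genes. From 30 to 90 min, all 9 treated libraries scored between 10.74 and 23.78 on it, and all 9 control libraries between -28.43 and -15.54. At 5 min, the library labelled control replicate 3 scored 22.43, among the treated libraries, and the library labelled treated replicate 2 scored -15.1, among the controls. The other 5 min libraries scored -19.29 and -14.8 in controls and 20.34 and 31.16 in treated fermenters. Control replicate 1 stood apart from 30 to 90 min on principal component 2, at 13.62 to 17.49, where the highest other library had 3.476. At 5 min it had 14.18, between the library labelled control replicate 3 at 9.16 and treated replicate 3 at 18.58. Its TMM factors were 0.8505 to 0.8637.

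**Figure D1:**
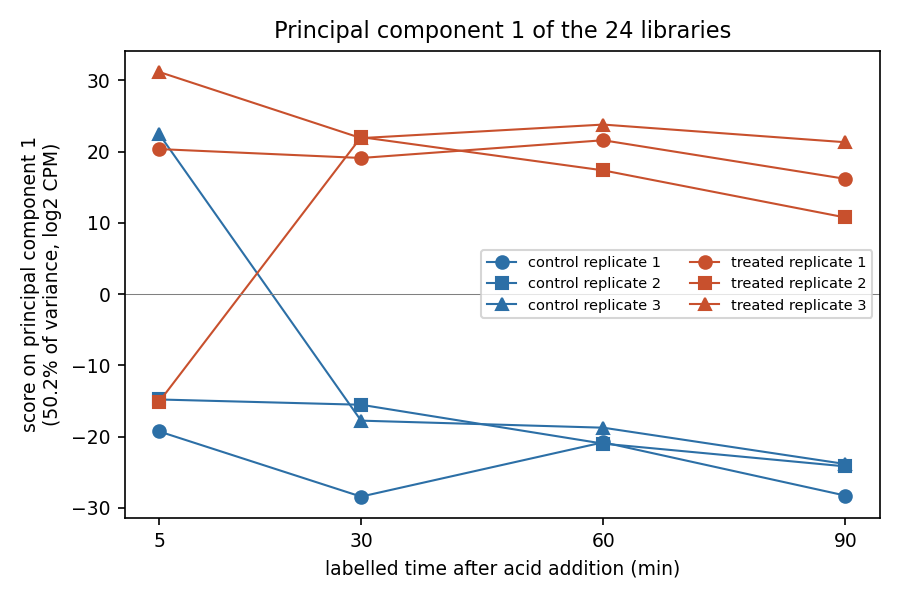
Score of each of the 24 libraries on principal component 1 of log2 CPM (vertical axis) against labelled time in min, with lines joining the libraries of 1 fermenter and blue for control, orange for treated. Libraries of the 2 setups lie apart from 30 min on, while at 5 min the library labelled control replicate 3 scored 22.43 and the library labelled treated replicate 2 scored -15.1.

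The comparison at 5 min asked which transcripts differed soonest after acid addition. The purine biosynthesis gene purH had a log2 fold change of -1.48 (SE 1.16), from 970.5 ± 773.9 CPM in controls to 348.4 ± 443.4 CPM in treated fermenters (SD, n = 3). The histidine biosynthesis gene hisB had -0.66 (SE 0.91), and rplL, which encodes ribosomal protein L7/L12, had 0.48 (SE 0.52). The chaperone genes dnaK and groEL had log2 fold changes of -0.44 and -0.34. Of the 5 ribosomal protein genes with a symbol, 4 lay higher in treated fermenters and none passed the test. Their camera p was 0.048, and with an estimated correlation the p was 0.199. By fry the p was 0.315, and 0.386 for mixed change. edgeR called 0 of 2633 genes, with 14 at an unadjusted p under 0.05, and DESeq2 called 0 with 31. Treated and control libraries did not overlap for 2.92% of genes, against 10% by chance.

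For purH at 5 min, the library labelled control replicate 3 had 112.2 CPM, against 1615 and 1184 CPM in the other controls, and the library labelled treated replicate 2 had 858.4 CPM, against 132.1 and 54.68 CPM in the other treated fermenters. For hisB these libraries had 28.9 and 198.3 CPM, against 257.5 and 140.5 CPM in the other controls and 39.8 and 31.11 CPM in the other treated fermenters. Without both libraries the log2 fold changes at 5 min were -3.91 (SE 0.52) for purH, -2.49 (SE 0.38) for hisB, -2.17 (SE 0.55) for leuD, of leucine biosynthesis, -1.42 (SE 0.35) for argC, of arginine biosynthesis, and 1.32 (SE 0.33) for rplL. edgeR then called 133 genes, 40 higher and 93 lower in treated fermenters. Among the gene symbols, purH and hisB alone were called. The edgeR adjusted p-values of leuD, argC and rplL were 0.0846, 0.0819 and 0.0831. The chaperone gene dnaK had -1.28 (SE 0.31, adjusted p 0.0818) and was not called either. These libraries were left out because of their place on the axis that separates treated from control libraries at later times, so the calls follow in large part from that choice and are no test of an effect at 5 min. The columns named 5 min may not hold that time, since the column names and the sample labels give different sets of times.

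At 30 min the comparison used all 3 fermenters of each setup, and purH fell most among the gene symbols. The bifunctional enzyme it encodes catalyses the last steps of purine biosynthesis, and its transcript went from 1279 ± 233.1 CPM in controls to 190.8 ± 12.74 CPM in treated fermenters (SD, n = 3), a log2 fold change of -2.74 (SE 0.21, adjusted p 0.000115). hisB, whose product acts in histidine biosynthesis, fell by 1.81 (SE 0.40, adjusted p 0.013), and dnaE, for a DNA polymerase III subunit, fell by 0.63 (SE 0.19, adjusted p 0.0433). The ribosomal protein gene rplL rose by 1.34 (SE 0.28, adjusted p 0.0114), tuf, for elongation factor Tu, by 0.79 (SE 0.23, adjusted p 0.0399), and rpsP, for ribosomal protein S16, by 0.74 (SE 0.22, adjusted p 0.0412). porA, a symbol used for a subunit of pyruvate:ferredoxin oxidoreductase, rose by 0.67 (SE 0.20, adjusted p 0.0419).

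Over the fixed lists at 30 min, 2 of the 5 ribosomal protein genes rose, and 2 did so when adjusted over the list alone. The other members rplS, rplB and rpmJ had log2 fold changes of 0.00, 0.26 and -0.57, and the camera p of the list was 0.278. By fry its p was 0.191, and 0.00729 for mixed change. The glycolysis and fermentation list held porA, which rose, and eno, for enolase, at 0.25 (SE 0.24). Of the 3 aminoacyl-tRNA synthetase genes 0 were called by edgeR, and 0 when adjusted over the list alone. In the biosynthesis lists with 1 symbol each, purH and hisB fell, leuD had -1.08 (SE 0.35, adjusted p 0.0551) and fell when adjusted over the list alone, argC had 0.05 and metX 0.12. The chaperone genes dnaK and groEL had -0.62 (SE 0.29) and 0.29 (SE 0.25) and were not called, and hppA, for a membrane-bound ion-pumping pyrophosphatase, had -0.40 (SE 0.21, adjusted p 0.191).

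In all, edgeR called 575 of 2670 genes at 30 min, of which 277 rose and 298 fell. At least 2-fold changes made up 176 of the rises and 201 of the falls. Treated and control libraries did not overlap for 40.9% of genes, against 10% by chance. The count was 379 without control replicate 3, 263 without treated replicate 2, 363 in a joint fit of all libraries and 332 by limma-voom. The calls of purH and rplL held with each library left out, though that of purH had an adjusted p of 0.0544 by limma-voom over all libraries. The call of hisB ended without treated replicate 2 (adjusted p 0.0576), and its log2 fold change was -1.15 without control replicate 1. Those of tuf and rpsP held only without control replicate 2 (adjusted p otherwise up to 0.13 and 0.131), that of dnaE only without control replicate 1 (up to 0.135), and that of porA ended whichever library was left out (up to 0.13). In the joint fit of all libraries the calls of hisB, dnaE, rpsP and porA ended, with adjusted p-values of 0.0578, 0.0913, 0.0607 and 0.102.

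**Figure D2:**
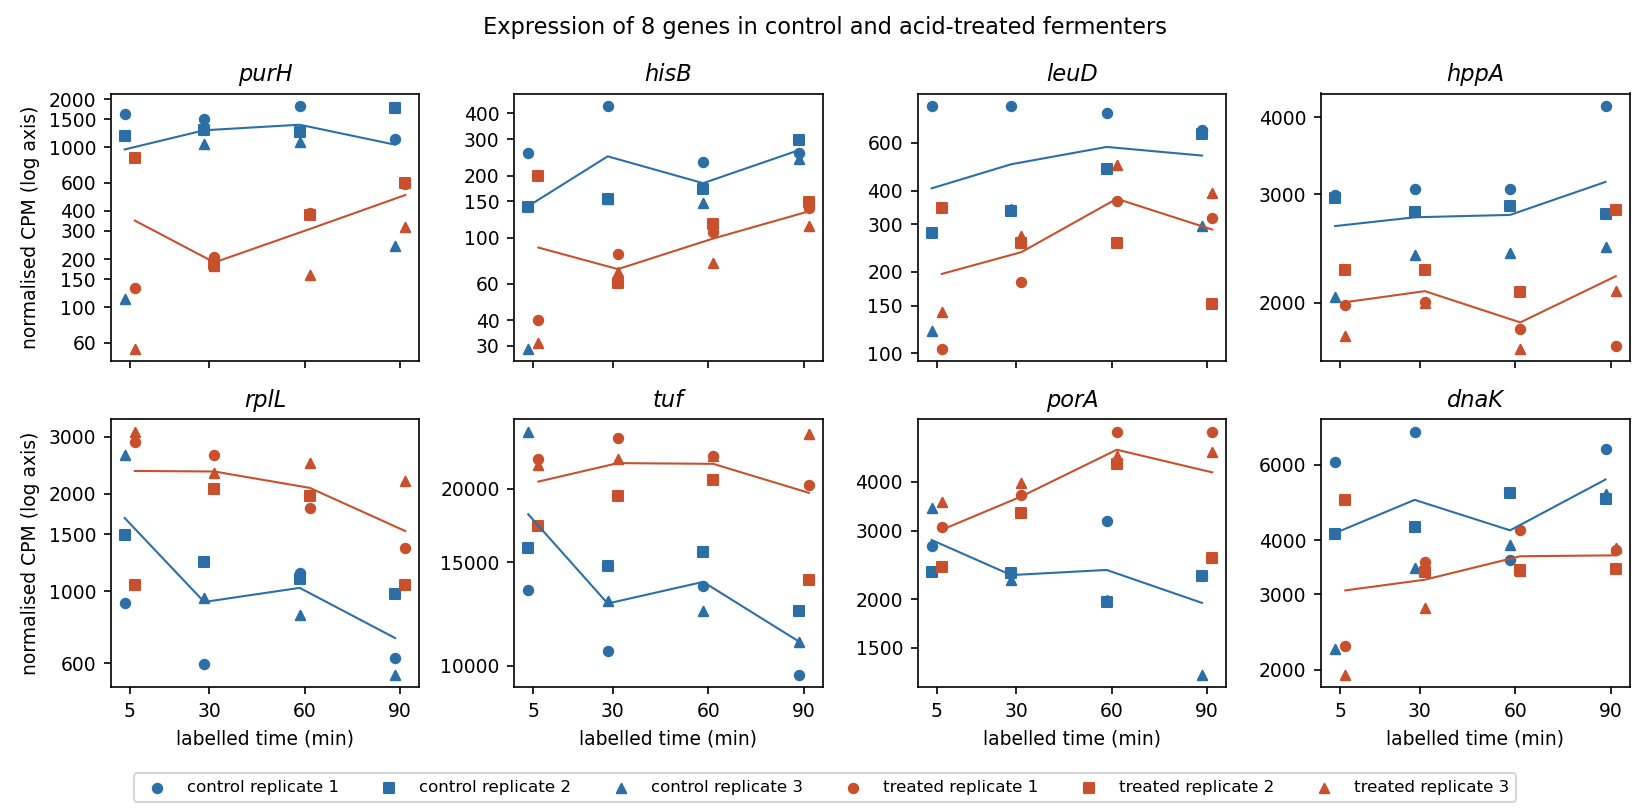
TMM-normalised CPM on a log axis (vertical) against labelled time in min for purH, hisB, leuD, hppA, rplL, tuf, porA and dnaK, with 1 point per library, offset sideways by setup, and lines through the means of 3 libraries. At 30 min purH had a mean of 1279 CPM in controls and 190.8 CPM in treated fermenters, and rplL had 927.7 and 2342 CPM.

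At 60 min purH was again lowest among the gene symbols, at 308.8 ± 130 CPM in treated fermenters and 1385 ± 387.1 CPM in controls (SD, n = 3), a log2 fold change of -2.17 (SE 0.36, adjusted p 0.00344). A gene for elongation factor G, fusA_2, fell by 1.49 (SE 0.41, adjusted p 0.027), while the other copy, fusA_1, had 0.62 (SE 0.21, adjusted p 0.059). How reads shared by these copies were counted is not given in the sources used here. hisB fell by 0.89 (SE 0.24, adjusted p 0.0244). porA rose from 2377 ± 690.3 to 4837 ± 485 CPM, a log2 fold change of 1.02 (SE 0.25, adjusted p 0.0158), and eno had 0.51 (SE 0.21, adjusted p 0.0996). Adjusted over the list alone, both of these glycolysis and fermentation genes rose.

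Among single genes for translation at 60 min, rplL rose by 1.02 (SE 0.22, adjusted p 0.00947), tsf, for elongation factor Ts, by 0.83 (SE 0.23, adjusted p 0.0286), tuf by 0.67 (SE 0.19, adjusted p 0.0332) and rplB, for ribosomal protein L2, by 0.63 (SE 0.20, adjusted p 0.0468). The phenylalanyl-tRNA synthetase gene pheS rose by 0.78 (SE 0.17, adjusted p 0.0109) and gatA, for a subunit of the amidotransferase that makes glutaminyl-tRNA, by 0.59 (SE 0.17, adjusted p 0.0308). Of the 5 ribosomal protein genes 2 rose, and 3 when adjusted over the list alone, while rplS and rpmJ had -0.37 and -0.03. The list had a camera p of 0.189 and a fry p of 0.0939, with a fry p of 0.00194 for mixed change. Of the 3 aminoacyl-tRNA synthetase genes pheS rose under both adjustments, and leuS and ileS had 0.46 and 0.17. metX, of methionine biosynthesis, rose by 0.65 (SE 0.20, adjusted p 0.0379). leuD had -0.64 (SE 0.28) and hppA -0.58 (SE 0.20, adjusted p 0.0633). Both fell when adjusted over their lists alone, where each is the only member. dnaK and groEL had -0.20 and 0.62 and were not called.

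At 60 min edgeR called 679 of 2682 genes, of which 332 rose and 347 fell, 197 and 218 of them at least 2-fold. Treated and control libraries did not overlap for 42.7% of genes, against 10% by chance. The count was 426 without control replicate 3 and 399 without treated replicate 1. The calls of purH, rplL and pheS held with each library left out. In the joint fit of all libraries, however, purH and rplL had adjusted p-values of 0.0801 and 0.0874. By limma-voom, also over all libraries, these values were 0.0926 and 0.107. The call of hisB ended without treated replicate 1 (adjusted p 0.0542), that of porA without control replicate 2, control replicate 3 or treated replicate 1 (up to 0.0779), and that of fusA_2 without control replicate 1, control replicate 2 or treated replicate 1 (up to 0.0826). The call of tsf held only without treated replicate 2 (otherwise up to 0.116), those of tuf and gatA only without control replicate 1 (up to 0.145 and 0.135), and those of metX and rplB ended whichever library was left out (up to 0.16 and 0.177), with 0.43 for metX without treated replicate 3. In the joint fit of all libraries the calls of hisB, fusA_2, tsf, tuf, rplB, gatA and metX ended too, with adjusted p-values of 0.0517 for tsf to 0.324 for hisB. Of the 31 calls of named genes over all times, 15 ended in this fit. Without the libraries labelled control replicate 3 and treated replicate 2 at 5 min, a choice made from their values, 5 ended in it.

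At 90 min hisB alone among the gene symbols passed the test, with a fall from 265.3 ± 28.03 CPM in controls to 134.3 ± 18.12 CPM in treated fermenters (SD, n = 3), a log2 fold change of -0.98 (SE 0.20, adjusted p 0.017). purH had -1.05 (SE 0.61, adjusted p 0.285), with 503.3 ± 159.5 CPM in treated fermenters and 1039 ± 757.8 CPM in controls. Control replicate 3 had 241.7 CPM of purH, below the lowest treated library at 319.2 CPM. The other controls had 1125 and 1750 CPM. The gene symbols that rose at 30 or 60 min did not pass the edgeR test at 90 min, with log2 fold changes of 1.11 for porA (SE 0.38, adjusted p 0.0905), 1.096 for rplL (SE 0.36, adjusted p 0.0824), 0.84 for tuf (SE 0.30, adjusted p 0.105) and 0.73 for pheS (SE 0.23, adjusted p 0.0733). rpsP had 0.53, gatA 0.42, rplB 0.36, tsf 0.35 and metX -0.17. DESeq2 called porA, rplL and pheS at 90 min, with adjusted p-values of 0.0209, 0.0179 and 0.0358. Of the 5 ribosomal protein genes edgeR called 0, and 0 when adjusted over the list alone, with a camera p of 0.289. By fry the p of the list was 0.402, and 0.103 for mixed change. When adjusted over the list alone, porA rose in the glycolysis and fermentation list and pheS among the aminoacyl-tRNA synthetases. hppA had -0.51 (SE 0.32), dnaK -0.59 (SE 0.26) and groEL 0.13 (SE 0.25).

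Over all rows, edgeR called 354 of 2685 genes at 90 min, 147 that rose and 207 that fell, 122 and 173 of them at least 2-fold. Treated and control libraries did not overlap for 36.2% of genes, against 10% by chance. The count was 578 by DESeq2, 671 in a joint fit without both doubtful 5 min libraries, 173 without control replicate 3, 159 without treated replicate 1 and 134 without treated replicate 3. The call of hisB ended without treated replicate 1 or treated replicate 3 (adjusted p up to 0.0827) and in the joint fit of all libraries (adjusted p 0.28).

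**Figure D3:**
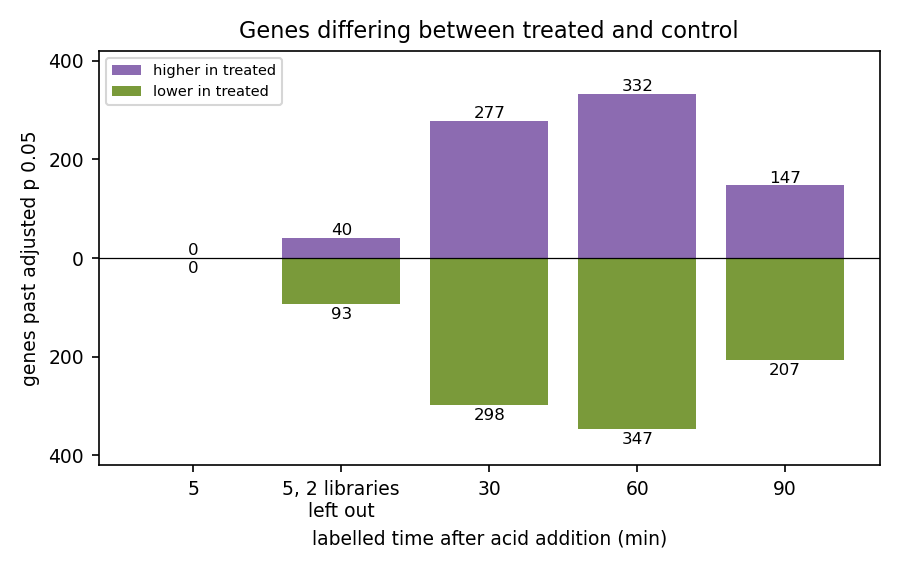
Number of genes higher (upward bars) and lower (downward bars) in treated than in control fermenters at an adjusted p under 0.05 by edgeR, at each labelled time in min. No gene passed at 5 min with all 6 libraries, and 40 were higher and 93 lower without the library labelled control replicate 3 and the library labelled treated replicate 2, which were left out for their place on the treated to control axis.

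From 30 to 90 min, 270 genes were called with 1 sign at all 3 times, of which 121 rose and 149 fell, and hisB was the gene symbol among them. The adjacent locus tags ATHE_RS00515 and ATHE_RS00520 rose most. ATHE_RS00515 rose from 28.71 ± 7.428 to 1211 ± 245.8 CPM at 30 min (SD, n = 3), with log2 fold changes of 5.397, 5.41 and 5.45 at the 3 times, and ATHE_RS00520 had 4.34, 4.64 and 4.51. ATHE_RS11320 fell, with -4.60, -4.41 and -5.35, and ATHE_RS10385 fell, with -6.49, -3.33 and -5.22, with 282.3 ± 435.2 CPM in controls at 30 min. Without control replicate 1, ATHE_RS10385 had -3.33 at 30 min and -2.57 at 90 min. Its calls at 30 and 90 min ended without any of the treated libraries (adjusted p up to 0.171 and 0.127), as did that at 60 min in the joint fit of all libraries (adjusted p 0.115). At 5 min these 4 tags were not called, with 0.93, 0.85, -1.05 and -1.77 in the order named.

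The rises called at 30 and 60 min shared 211 genes and the falls 233, where independent lists would share 34.8 and 38.4. The lists come from the same 6 fermenters and are not independent, so such values are no chance level. At 30 and 90 min they shared 127 and 160 (15.3 and 22.9 for independent lists), and at 60 and 90 min 131 and 168 (18.2 and 26.6). There were 0 genes called in opposite directions between any of these times. Across 2706 genes, which are not independent replicates, the fold changes at 30 and 60 min had a Pearson r of 0.905 and a Spearman rho of 0.874. The other 9 splits of the same 6 fermenters gave r between 0.638 and 0.805 for these times. Between 30 and 90 min r was 0.901 (other splits 0.606 to 0.791), and between 60 and 90 min 0.905 (0.604 to 0.847). Between 5 and 30 min r was 0.697, within the other splits (-0.142 to 0.779). Every other split still has most fermenters of a setup on the same side, so it keeps part of the treatment contrast. The ranges of the other splits are therefore no chance level. They cannot decide if the effects at 5 and 30 min are alike.

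Whether the treatment effect itself differed between times was tested with the fermenter as a block. No gene symbol passed. The closest was eno, whose effect at 90 min exceeded that at 5 min by 0.68 (SE 0.17, adjusted p 0.0593), and purH had a difference of 0.82 (SE 1.004, adjusted p 0.706). The joint test called 20 of 2706 genes, all with a locus tag alone, and the contrast of 90 against 5 min called 53, of which 23 were higher and 30 lower at 90 min relative to 5 min. DESeq2 called 92 in the joint test and 114 in the contrast, and edgeR without the fermenter as a block called 2 and 4. Without both doubtful libraries, whose removal was chosen from their values, the joint test called 27 genes, 11 of them among the 20, and the contrast called 97, with a difference of 2.67 (SE 0.63) for purH and 1.81 (SE 0.41) for argC. From 30 to 90 min only, edgeR called 0 genes in the joint test, with 226 at an unadjusted p under 0.05, and no other tool was run on these times. The contrast of 90 against 30 min called 1 gene, a locus tag, with 243 at an unadjusted p under 0.05. Without control fermenters 1, 2 and 3 in turn the joint test called 2, 3 and 9 genes and the contrast 16, 10 and 14. Without treated fermenters 1, 2 and 3 the joint test called 10, 12 and 2 genes and the contrast 27, 41 and 27.

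Control fermenters sampled at 90 and at 5 min give the background of change with time at pH 7.2. The gene symbols with the lowest p were tuf, with a log2 fold change of -0.78 (SE 0.20, adjusted p 0.109), xylF, for a sugar-binding protein of xylose uptake, with 0.94 (SE 0.25, adjusted p 0.109), and rplL, with -1.28 (SE 0.35, adjusted p 0.112). Without the library labelled control replicate 3 at 5 min, tuf had -0.47, xylF 1.05 and rplL -0.74. edgeR called 0 of 2698 genes, with 707 at an unadjusted p under 0.05. DESeq2 called 251, among them tuf, xylF, rplL, rpsP and fusA_1, and edgeR without the library labelled control replicate 3 at 5 min called 2, both with a locus tag alone.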

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

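The tests of an exchange of libraries, the splits at 5 min and all fits that leave out the doubtful 5 min libraries were chosen only after the result was seen. The effect of acid treatment differed between times for 20 genes in the joint test and for 53 genes in the contrast of 90 against 5 min, and both stand out because the difference between times was itself tested. Among the 10 splits of the 6 fermenters into 3 and 3, 1 gave as many genes as the 20 of the joint test, and the highest other split gave 14. For the contrast 2 of 10 gave as many as 53, and the highest other gave 114. These splits are too few for a share under 0.05. The split with 14 and 114 genes sets control fermenters 1 and 2 with treated fermenter 2 against the rest. It points to a structure of the samples that crosses the labelled setups, and places the libraries labelled control replicate 3 and treated replicate 2 at 5 min as principal component 1 does, so it is no separate evidence.

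The 5 min libraries may carry part of this difference: from 30 to 90 min alone, with fewer libraries in the fit, the joint test called 0 genes by edgeR, with 226 at an unadjusted p under 0.05 and no other tool run, and the contrast of 90 against 30 min called 1. Without the 2 doubtful libraries the joint test called 27, and 11 of the 20 were among them. On a scale over 270 genes where 0 is the mean control and 1 the mean treated library of 30 to 90 min, the library labelled control replicate 3 at 5 min lay at 0.998 and the library labelled treated replicate 2 at 0.184. Counting depth is argued against as the whole reason for 0 calls at 5 min, since the 30 min libraries thinned to the 5 min totals gave 567 genes. Of the 2 doubtful libraries 0 matched the other's fermenter best at any of the 3 later times, and the library labelled treated replicate 2 matched control fermenter 2 (r of 0.412, 0.378 and 0.301), but only 3 of 4 libraries in place matched their own at all 3 times, so an exchange with each other stays open. A different course of the response could apply to treated fermenter 2 alone, since control fermenter 3 received no acid by its label. That course and a difference between named and true sampling time were not tested and stay open. Over log2 CPM, the library labelled control replicate 3 at 5 min correlated at 0.9927 with treated replicate 1 at 5 min. With control replicate 3 at 30 min it correlated at 0.9493.

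At 5 min edgeR called 0 genes in the real split (14 at an unadjusted p under 0.05, and 0 called by DESeq2), so all 10 of the 10 splits give at least as many whatever the data, and the count of splits says nothing. The highest other gave 700, with control replicates 1 and 2 and treated replicate 2 against the rest, which restates the place of these libraries on principal component 1.

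Fewer genes were called at 90 min (354) than at 60 min (679), and the difference between these counts was not tested. A wider spread between fermenters at 90 min is a candidate explanation, with a biological coefficient of variation 1.21 times that at 60 min (1.17 to 1.35 with each fermenter left out). A smaller effect is argued against, since the median effect of the 575 genes called at 30 min was 0.975 times that at 60 min (0.93 to 1.01). What widened the spread was not tested. At 30, 60 and 90 min, 1 of 10 splits each gave as many genes as the real 575, 679 and 354, and the highest other gave 0, too few splits for a share under 0.05.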

How the results depend on the processing

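The settings that leave out the doubtful libraries or the 5 min libraries are tests chosen after seeing the data, and the doubtful libraries were picked from their place on the treated to control axis, which favours calls at 5 min. At 5 min every planned setting called 0 genes, while 133 were called without both doubtful libraries (chosen after) and 507 in a joint fit without them (chosen after). At 30 min the count was 363 in a joint fit of all libraries, 332 by limma-voom, 377 with an absolute log2 fold change of at least 1, and 263 to 581 with each library left out. At 60 min it was 415 with that minimum change and 399 to 722 with each library left out. At 90 min it was 578 by DESeq2, 671 in the joint fit without the doubtful libraries and 134 to 405 with each library left out. The joint test over times gave 92 by DESeq2, 2 with no replicate block (here, without the fermenter as a block), 0 from 30 to 90 min only and 2 to 12 with each fermenter left out; the contrast of 90 against 5 min gave 114, 4 without the fermenter block, 97 without the doubtful libraries and 10 to 41. Change in controls gave 251 by DESeq2, 2 without the doubtful control library and 0 to 2 with each fermenter left out. The minimum change lowers counts by construction; for the others the cause was not tested. Apart from the replicate block, other planned settings stayed within 1.5 times the count. Of 31 calls of named genes, 15 held with every library left out and 0 changed sign: 5 of the 19 calls of gene symbols and 10 of the 12 of locus tags, which were picked as the largest changes. Calls lost were 15 in the joint fit of all libraries, 5 in that fit without both doubtful libraries (chosen after) and 13 by limma-voom. The limma-voom fit also covered all libraries and was not run without the doubtful ones. The alternatives at 10 min were not run.

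The replicate block gave 0, 512, 712 and 151 genes at 5, 30, 60 and 90 min. The labels do not say that a number is shared between setups. Deviations of same-numbered libraries correlated at -0.47 to 0.676 at 5 min, where the 2 doubtful libraries lie out of place. From 30 to 90 min they correlated at -0.233 to 0.265, and not every library correlated best with its own number. No pairing by number held across times, though 3 libraries per setup are too few to exclude one. Under the block the calls of 7 named genes and times were lost, and hppA at 60 min passed (adjusted p 0.0498 by edgeR). The camera p of the biosynthesis set, chosen after seeing the data, was 0.0128 at 5 min, and at 30 min its adjusted value was 0.0454, while with an estimated correlation and no block these were 0.39 and 0.402. Thinning the 30 min libraries to the 5 min totals gave 567 genes against 575.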

Other observations

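The tests of the biosynthesis genes as a set, of the ribosomal protein and tRNA synthetase genes as a set, and of both without the doubtful libraries were chosen only after the result was seen. Other gene groups at pH 6.0 gave the following values. The 4 flagellar genes flgL, flhA, flgC and flgG had median log2 fold changes of -0.02, -0.24, -0.34 and -0.39 at 5, 30, 60 and 90 min, and edgeR called 0 of them at any time, also when adjusted over the list alone. murD, of peptidoglycan synthesis, had -0.46 at 60 min and fell when adjusted over the list alone, where it is the only member. pyrH, of pyrimidine biosynthesis, had 0.14, 0.21 and 0.31 at 30, 60 and 90 min, pstB, of phosphate uptake, had -0.15, 0.34 and -0.01, and cbiO, of the cobalamin and metal uptake lists, had 0.17, 0.23 and 0.01, none of them called. xylF, of carbohydrate uptake, had 0.64, -0.32 and 0.07 and was not called, and spoVFB, of sporulation, was tested at 90 min only, with 0.46. The 5 amino acid and purine biosynthesis symbols purH, argC, leuD, hisB and metX as a set had a camera p of 0.0855, 0.028, 0.326 and 0.16 at 5, 30, 60 and 90 min. The value at 30 min was 0.056 after adjustment over both of these sets, and 0.201 with an estimated correlation. At 5 min it was 0.39 with all libraries and an estimated correlation. Without both doubtful libraries it was 0.00565 (adjusted 0.0113) at 5 min. They were left out for their place on the treated to control axis, so that value is no test of an effect. By fry, with all libraries, the p of this set was 0.553, 0.00657, 0.106 and 0.141 at 5, 30, 60 and 90 min. For mixed change the fry p was 0.443, 0.000149, 0.00576 and 0.0118. The 8 ribosomal protein and tRNA synthetase symbols as a set had a camera p of 0.0197, 0.12, 0.0472 and 0.0866 at 5, 30, 60 and 90 min, adjusted to 0.0393 at 5 min and 0.0944 at 60 min. With an estimated correlation these were 0.275 at 5 min and 0.412 at 60 min. Without both doubtful libraries, with the same limit, the value at 5 min was 0.0166. By fry, with all libraries, this set had a p of 0.395, 0.106, 0.0424 and 0.233 at 5, 30, 60 and 90 min. For mixed change the fry p was 0.435, 0.00756, 0.00206 and 0.0607.

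Genes next to each other in the table changed together. At 30 min 244 neighbouring pairs were called in 1 direction, against a mean of 61.8 and a highest value of 97 in 10000 permutations of the row order (permutation p 1e-04, the smallest they can give). The counts were 328 at 60 min (mean 85.7) and 152 at 90 min (mean 23.9), and 14, 20 and 7 pairs were called in opposite directions. purH lay in a run of 10 genes that fell at 30 and at 60 min, and hisB in runs of 13, 10 and 9 genes that fell at 30, 60 and 90 min. Shared transcription of neighbouring genes in operons may account for the 244 pairs; the strand and the operons were not examined, and reads that span neighbouring genes stay open.

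Change with time in control fermenters did not run in the direction of the treatment effect, and an opposite direction was not tested. The log2 fold changes of control libraries at 90 over 30 min and of treated over control libraries at 60 min had a Pearson r of -0.256 and a Spearman rho of -0.263 across 2706 genes, which are not independent replicates (r of -0.37 to -0.0678 with each control fermenter left out). For control fermenters at 90 against 5 min edgeR called 0 genes (707 at an unadjusted p under 0.05, 251 called by DESeq2), so all 4 exchanges of these times within fermenters give at least as many whatever the data, and this count says nothing. The highest other gave 0.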
